A study of Homo sapiens with 12 samples.

How the data were processed

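RNA was measured in HEK293 cells, a human embryonic kidney line grown with 10% serum, and in the extracellular vesicles (EVs) that they release. Per the labels' protocols, cells were transfected by lipofection for 48 h with a vector set named 4EC1, whose name lists eGFP, EIF4E, YTHDF1, GBP1 and CD9, and were then kept in normoxia or for 24 h in a hypoxia chamber. What GBP1 stands for in that name is not given in the sources used here. Cellular RNA was taken with TRIzol and EV RNA with an exoRNeasy midi kit, and both were made into stranded total RNA libraries, per the same protocols. The 4 groups (normoxia cells, hypoxia cells, normoxia EVs and hypoxia EVs) had 3 replicates each, 12 libraries in all, assigned by the sample titles. Nothing in the labels says that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

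The deposited values are a signal per gene, which the authors made by dividing read counts by a single factor per library. This was read from the values, since the low values of each library were whole multiples of a single step. The submitters' processing notes name Bowtie 0.12.2, DESeq2 1.30.1 and the builds hg38 and GRCh38. The counter, the annotation, the strand setting and any filter are not given in the sources used here. Reads of genes that overlap, lie antisense to another gene or have near-identical copies (histone genes, small RNA genes, ribosomal protein genes with processed pseudogenes, GOLGA6L2 and other multigene families) may therefore have been split between genes, and values of such genes are uncertain. The table held 57773 gene IDs. Of these, 52338 matched a name, a position and a length in GENCODE release 29 on GRCh38, and 5435 (9.41%) did not. The 37 mitochondrial IDs were listed at 0 in all 12 libraries, so the list of 13 mitochondrially encoded mRNAs could not be tested.

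Whole reads were recovered by dividing each library by its step, and 100% of the values came out whole within a tolerance of 0.01. The 12 same-group pairs differed by more than counting noise (chi-square per degree of freedom 5.27 to 14.8), so each library was counted as a sample of its own. A read was worth 0.512 deposited units on average in normoxia cells, 0.527 in hypoxia cells, 2.04 in normoxia EVs and 1.79 in hypoxia EVs, where it ranged from 1.34 to 2.52. A count of 0 allows up to 3 reads, which is 1.54, 1.58, 6.13 and 5.38 units in the same groups. Reads carry no molecular identifiers, so such floors cover counting error only.

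The main test was limma-trend (limma 3.58.1, R 4.3.3) on log2(value + 1), with Benjamini-Hochberg adjustment and a threshold of 0.05, over genes with a mean of at least 10 in the libraries of the fit. Fold changes are on that log2(value + 1) scale, which understates the change of low genes. Hypoxia was compared with normoxia within the 6 cell libraries and within the 6 EV libraries. EVs were compared with cells over all 12 libraries as the mean of the 2 EV groups minus the mean of the 2 cell groups. The difference of the hypoxia responses, EV minus cell, was tested as an interaction in the same fit. Makeup of the libraries was tested with exact two-sided permutation tests (30 in all, Benjamini-Hochberg adjusted), and 3 against 3 cannot give a p under 0.1.

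The genes named are the 10 higher and the 10 lower (5 and 5 for the interaction) with the largest lower 95% bound of the absolute log2 fold change, the absolute value less 1.96 SE, among named protein-coding genes past the threshold with a mean of at least 100 and groups that did not overlap. To these came 16 fixed genes (VEGFA, CA9, ADM, SLC2A1, BNIP3, LDHA, PDK1, ANKRD37, EGLN3, NDRG1, HIF1A, EIF4E, YTHDF1, CD9, ACTB and GAPDH) and up to 4 genes with the smallest p from each list. Some genes that this rule gives are not reported here. The 18 gene lists were targets of the hypoxia-inducible factors (HIF), glycolysis, nuclear-encoded oxidative phosphorylation (OXPHOS), mitochondrially encoded mRNAs, cytosolic ribosomal proteins, cholesterol synthesis, stress response, proliferation, replication-dependent histones, homologous recombination and mismatch repair, nuclear-retained lncRNAs, small structured noncoding RNAs, EV biogenesis, eIF4E-sensitive mRNAs, interferon response, the construct genes EIF4E, YTHDF1 and CD9, blood and immune markers, and liver and plasma protein markers. VEGFA is in the HIF and eIF4E lists, VLDLR in the HIF and stress lists, BIRC5 in the proliferation and eIF4E lists, NBN in the repair and eIF4E lists, and CD9 in the EV biogenesis and construct lists. The design and, unless said otherwise, the other settings named below were fixed before the data were examined. Lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, which tests whether a list moves one way on balance.

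The fits were repeated with pseudocounts of 0.5 and 5, a filter mean of 50 or none, TMM factors, equal totals and median of ratios within the fit, library weights, the replicate number as a block, each library left out in turn, all 12 libraries in a single fit, and edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 on the recovered reads. On those reads edgeR called 1891 genes higher and 2606 lower in hypoxia cells, 1026 and 2477 in hypoxia EVs, and 10143 and 8284 in EVs against cells. DESeq2 called 1926 and 2515, 1552 and 2990, and 11464 and 7481 in the same comparisons. Chosen after the data were seen was the removal of a background per kb of gene from the EV libraries. It was estimated as the density on protein-coding genes with a cell mean above 1 and at most 20, less that of the cell libraries. The list tests with TMM and with equal totals were not among the settings fixed beforehand either.

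The fits were tested on simulated data with 2-fold and 4-fold changes in known genes. At the depth of the cell libraries limma recovered 76.5% of the 2-fold and 95.9% of the 4-fold changes over 16901 genes, and 6.63% of its calls were false. For EVs these shares were 8.79% and 49.5% over 26251 genes with 1.72% false. For EVs against cells they were 50.0% and 74.5% over 23273 genes with 2.50% false, and for the interaction 10.3% and 35.5% over 23144 genes with 10.4% false. Each gene was simulated on its own, with no shift shared by the genes of a library. The normoxia EV libraries differed by such a shift, so the false shares need not hold for calls that use EV libraries. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.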

Results

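RNA of HEK293 cells carrying the 4EC1 vectors and RNA of the EVs they released were sequenced after normoxia or hypoxia, in 3 libraries per group. The series asks whether mRNA loaded into EVs can report on living cells without lysing them. Cell libraries held 18059381 to 23400813 reads, normoxia EV libraries 5266244 to 7001767 and hypoxia EV libraries 3259453 to 6129782. On average 37306 genes had a value above 0 in normoxia cells, 39343 in hypoxia cells, 32170 in normoxia EVs and 41053 in hypoxia EVs (n = 3 each).

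Reads on EIF4E, YTHDF1 and CD9, which encode the cap-binding translation factor, an m6A reader and a tetraspanin of EV membranes, made up a larger part of EV RNA than of cellular RNA. They took 6.61% ± 0.588 of the reads in cells and 22.6% ± 1.64 in EVs (SD, n = 6 each), a ratio of 3.41 (exact two-sided permutation test, p = 0.00216, adjusted p = 0.0108, higher in 6 of 6 EV libraries). YTHDF1 alone took 2.32% in normoxia cells and 9.06% in normoxia EVs, and CD9 0.754% and 3.37% (n = 3 each). Reads of the vectors' mRNA, of any plasmid carried along and of the endogenous genes cannot be separated here. Ribosomal protein mRNAs took a smaller part of EV reads, 2.54% against 4.06% in cells (n = 6 each, exact two-sided permutation test, p = 0.00216, adjusted p = 0.0108). Part of this follows from the share of the highest genes. Without the 10 highest genes they took 3.69% in EVs and 4.61% in cells, and normoxia EV replicate 2 (4.67%) lay above the 3 hypoxia cell libraries (at most 4.45%). Processed pseudogenes took 1.28% of EV reads and 0.421% of cell reads (n = 6 each, exact two-sided permutation test, p = 0.00216, adjusted p = 0.0108). HIF targets together took 0.172% of the reads in normoxia cells and 0.414% in hypoxia cells, 2.40 times as much. In EVs they took 0.123% and 0.177%, 1.44 times as much (exact two-sided permutation test, p = 0.1 for each, the smallest 3 against 3 can give). Small nucleolar RNAs took 0.322% of the reads in normoxia EVs and 0.134% in hypoxia EVs (exact two-sided permutation test, p = 0.1).

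Genes that are near silent in the cells held reads in the EVs. Over 6020 protein-coding genes with a mean of at most 20 in cells, the read density (RPKM) was 0.139 ± 0.0159 in normoxia cells, 0.191 ± 0.0177 in hypoxia cells, 0.707 ± 0.433 in normoxia EVs and 2.15 ± 0.0727 in hypoxia EVs (SD, n = 3 each). The normoxia EV libraries differed among themselves, at 0.355, 0.576 and 1.19 for replicates 1, 2 and 3, so their mean rests on replicate 3. EVs held 8.63 times the density of cells (n = 6 each, exact two-sided permutation test, p = 0.00216, adjusted p = 0.0108). As the genes were picked for low values in these same cell libraries, the direction was favoured in advance and this p does not test it. The choice did not use the EV libraries, so the difference between the EV groups does not follow from it. Thinned to equal depth, 29758 genes were seen in normoxia EVs and 39606 in hypoxia EVs, against 27068 and 29480 in cells.

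**Figure D1:**
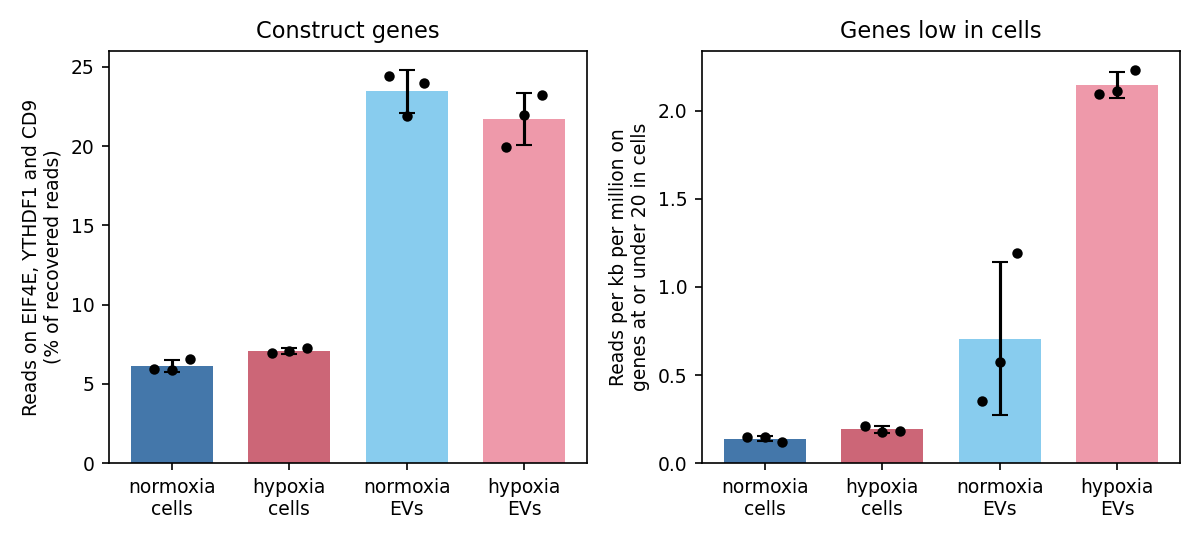
Left, share of recovered reads (%) on EIF4E, YTHDF1 and CD9, and right, RPKM on 6020 protein-coding genes with a mean of at most 20 in cells, for the 4 groups (bars, mean; lines, SD; points, the 3 libraries of each group). The construct genes take 22.6% of the reads in EVs and 6.61% in cells, and the density on low genes is 2.15 in hypoxia EVs.

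**Figure D2:**
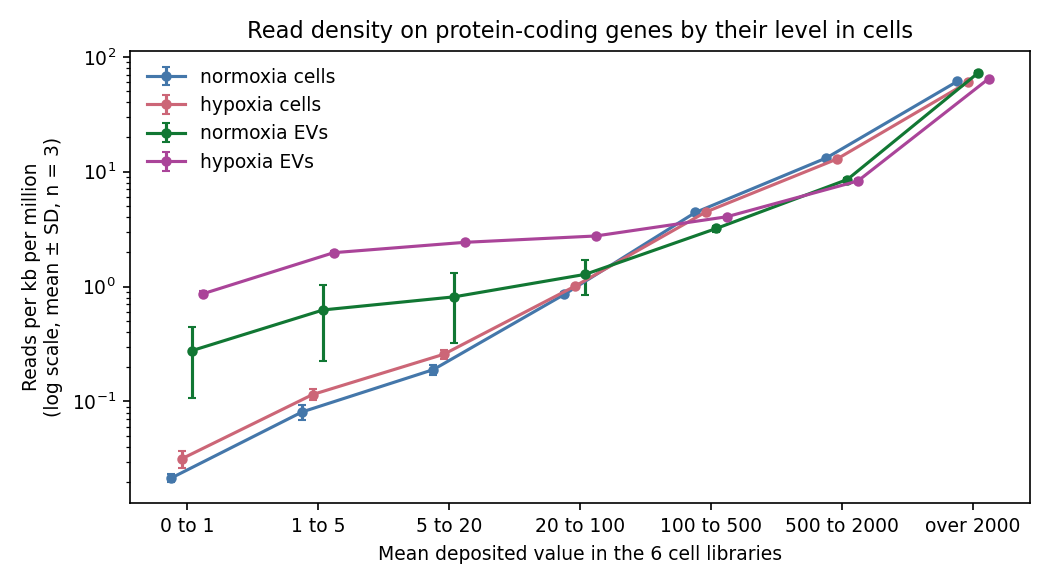
Read density (RPKM, log scale) on protein-coding genes in 7 classes of their mean deposited value in the 6 cell libraries, as mean ± SD of 3 libraries per group. The EV lines, hypoxia EVs most, lie above the cell lines in the classes up to a mean of 100 and close to them in the higher ones.

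In the cells, hypoxia was compared with normoxia to see what it did to their RNA. Transcripts of the known response to low oxygen were higher in hypoxia. HILPDA, a lipid droplet protein (ENSG00000135245, chromosome 7, 128455849 to 128458418, GRCh38), stood at 100.4 ± 8.38 in normoxia and 508 ± 52.3 in hypoxia (SD, n = 3 each, log2 fold change 2.32, SE 0.12, limma adjusted p = 3.63e-25). PLOD2, a collagen lysyl hydroxylase (ENSG00000152952, chromosome 3, 146069440 to 146163653), rose from 925 ± 47.1 to 3162 ± 94.8 (SD, n = 3 each, log2 fold change 1.77, SE 0.06, limma adjusted p = 4.28e-34). VEGFA, the angiogenic growth factor (ENSG00000112715, chromosome 6, 43770184 to 43786487), rose from 718 ± 53.8 to 1539 ± 41.1 (SD, n = 3 each, 1.10, SE 0.07). The groups did not overlap in any library for these genes. PFKFB4 (2.28), BHLHE40 (2.11), PPFIA4 (2.11), DDIT4 (2.02), P4HA1 (1.92), SLC2A3 (1.91) and PDK1 (1.71) rose on the log2 scale as well. So did BNIP3 (1.67), SLC2A1 (1.27), ADM (1.06), NDRG1 (1.01) and EGLN3 (0.78). The oncogene MYC (ENSG00000136997, chromosome 8, 127735434 to 127741434) fell from 1395 ± 67.7 to 526 ± 49.6 (SD, n = 3 each, log2 fold change -1.41, SE 0.08, limma adjusted p = 1.29e-24). Others that fell were the linker histone gene H1-3 (-1.54), the nuclear receptor gene RORB (-1.39), CITED1 (-1.20), H3C12 (-1.20), USP46 (-1.10), the chaperone gene HSPA8 (-1.08), LRATD2 (-1.02), NPM3 (-1.01), IRS4 (-0.97) and HIF1A itself (-0.46). Of the construct genes, EIF4E (0.09, limma adjusted p = 0.293) and YTHDF1 (0.04, limma adjusted p = 0.623) did not pass. CD9 rose by 0.18 (limma adjusted p = 0.0062), a call that ended without normoxia cell replicate 2 (0.15) or hypoxia cell replicate 3 (0.14).

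Of the 46 HIF targets tested in cells, 39 rose, and 41 did when adjusted over the list alone (median 1.07, camera adjusted p = 3.06e-72). Replication-dependent histones went the other way, 13 of 16 fell, likewise 13 adjusted over the list alone (median -0.49, camera adjusted p = 3.54e-14), with H2BC11 at -0.80 and H2BC4 at -0.75. These are the 2 lists whose camera call held with an estimated correlation (adjusted p = 0.00128 and 0.0124). Glycolysis had 13 of 20 genes higher and 2 lower, the same counts adjusted over the list alone, with PGK1 at 1.26, LDHA at 0.94 and ALDOA at 0.90 (median 0.36, camera adjusted p = 6.02e-18). Its adjusted p = 0.125 with an estimated correlation. Cholesterol synthesis had 11 of 24 higher and 3 lower, also adjusted over the list alone, with IDI1 at 0.73, MSMO1 at 0.66 and SQLE, the squalene epoxidase gene, at 0.42 (median 0.13, camera adjusted p = 0.000124, adjusted p = 0.0816 with an estimated correlation). Nuclear OXPHOS genes fell in 32 of 46 cases and in 34 adjusted over the list alone, with UQCRC2 at -0.49 and ATP5F1C at -0.48 (median -0.30, camera adjusted p = 5.31e-09, adjusted p = 0.125 with an estimated correlation). Ribosomal protein genes fell in 71 of 78 cases and in 73 adjusted over the list alone, with RPL24 at -0.62 and RPL6 at -0.47 (median -0.31, camera adjusted p = 8.38e-25, adjusted p = 0.128 with an estimated correlation). Proliferation genes fell in 27 of 41 cases against 2 higher, 30 and 3 adjusted over the list alone, with CCNB1 at -0.57, MCM5 at -0.52 and PLK1 at -0.48 (median -0.28, camera adjusted p = 8.62e-08, adjusted p = 0.228 with an estimated correlation). With equal totals 18 OXPHOS, 48 ribosomal protein and 19 proliferation genes were lower.

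Nuclear-retained lncRNAs were split, 6 of 17 higher and 3 lower (6 and 4 adjusted over the list alone), with MALAT1 at 0.92, NEAT1, the scaffold of paraspeckles, at 0.66 and GAS5 at -0.44 (median 0.03, camera adjusted p = 0.0326, adjusted p = 0.295 with an estimated correlation). Among eIF4E-sensitive mRNAs 8 of 19 fell and 1, VEGFA, rose, the same adjusted over the list alone, with CCND1 at -0.56 (median -0.19, camera adjusted p = 0.0166, adjusted p = 0.358 with an estimated correlation). Without normoxia cell replicate 3 that list's camera adjusted p was 0.0534. The remaining lists did not pass camera in cells. Stress response genes had 5 of 27 higher and 4 lower, unchanged adjusted over the list alone, ATF3 at 0.79, VLDLR at 0.76, ATF4 at -0.29 and SLC7A11 at -0.75. Their median was -0.05, their mean 0.03 and camera pointed up (adjusted p = 0.208), and the median turned to 0.01 with TMM and 0.08 with equal totals. Homologous recombination and mismatch repair had 8 of 24 lower and 1 higher (10 and 1 adjusted over the list alone), BLM at -0.32 and BRIP1 at 0.31 (median -0.12, 0.01 with equal totals, camera adjusted p = 0.498). Small structured RNAs had 3 of 17 lower, also adjusted over the list alone, with the Y RNA genes RNY3 at -1.44 and RNY1 at -0.55 (camera adjusted p = 0.581, and 0.0124 without hypoxia cell replicate 3). Their median was -0.04, 0.01 with TMM and 0.08 with equal totals. EV biogenesis had 9 of 30 lower and 3 higher (13 and 4 adjusted over the list alone), RAB11A at -0.47 and VPS4A at -0.37 (median -0.16, camera adjusted p = 0.284). Interferon response had 2 of 24 higher and 2 lower (1 and 2 adjusted over the list alone, median 0.03, camera adjusted p = 0.208). Of the construct genes 1 of 3 was higher, also adjusted over the list alone (median 0.09, camera adjusted p = 0.14, and 0.000492 without normoxia cell replicate 3). Cells expressed 4 of the 20 blood and 4 of the 17 liver markers above the filter. Of the blood markers 1 was higher, also adjusted over the list alone, with a median of -0.24, a mean of -0.12 and camera pointing up (adjusted p = 0.606). Of the liver markers 1 was higher and 3 adjusted over the list alone (median 0.96, camera adjusted p = 0.119).

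In all, 1383 genes rose and 3871 fell of 17260 tested in cells (limma), 353 and 78 of them by at least 2-fold, and the groups did not overlap for 6956 genes (40.3%, against 10% by chance). The excess of lower genes depends on the scaling. With equal totals 2304 were higher and 2043 lower (median log2 fold change 0.06 against -0.07), edgeR gave 1891 and 2606, and DESeq2 1926 and 2515. In a fit of all 12 libraries, which shares the wider spread of the EVs, 59 were higher and 25 lower, and 23 named genes past the threshold, HILPDA, PLOD2, VEGFA and MYC among them, kept their call there.

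**Figure D3:**
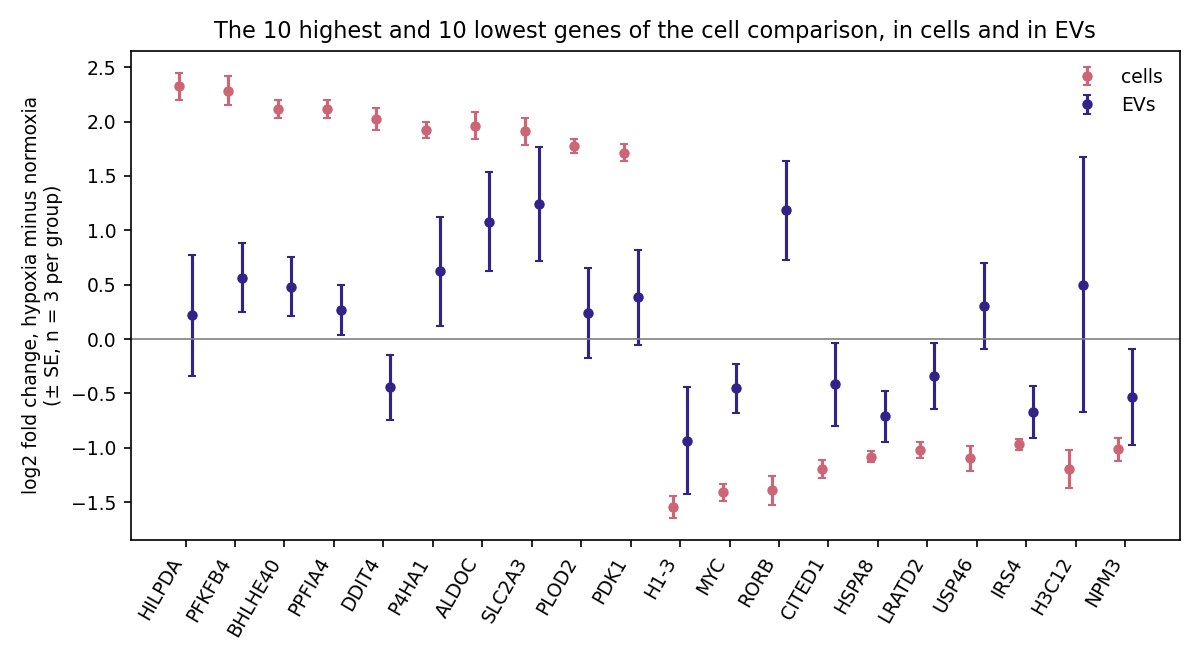
Log2 fold change, hypoxia minus normoxia (± SE, n = 3 per group), of the 10 highest and 10 lowest genes of the cell comparison, in cells and in EVs. HILPDA stands at 2.32 in cells and MYC at -1.41, while most EV values lie closer to 0 with wider errors.

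In the EVs, hypoxia was compared with normoxia to see what extracellular RNA shows of the same treatment. The clearest change was in SNORD17, a small nucleolar RNA (ENSG00000212232, chromosome 20, 17962710 to 17962946, GRCh38), which fell from 6046 ± 2033 to 648 ± 15.6 (SD, n = 3 each, log2 fold change -3.16, SE 0.24, limma adjusted p = 2.1e-08). In cells it stood at 1759 ± 113 and 1734 ± 266 (SD, n = 3 each). The EV groups did not overlap in any library for SNORD17 or for the genes named next. SNORA73B fell by 2.21, RNU4-2, a spliceosomal U4 RNA, by 1.48 and TERC, the telomerase RNA, by 1.66. Of mRNAs, PAWR, a pro-apoptotic regulator (ENSG00000177425, chromosome 12, 79574979 to 79691097), fell from 1290 ± 350 to 440 ± 61.4 (SD, n = 3 each, log2 fold change -1.52, SE 0.24, limma adjusted p = 0.00209). GABBR1 (-1.72), TMEM123 (-1.62), PRKAA2 (-1.57), OTUD4 (-1.54), PPP2R3B (-1.50), KIF20B (-1.48), TTF1 (-1.41) and the splicing genes DDX46 (-1.41) and PRPF38B (-1.31) fell as well. The genes that rose most were near silent in cells. STYXL2 (ENSG00000198842, chromosome 1, 167094045 to 167129165) stood at 8.25 ± 2.19 and 16.8 ± 6.95 in normoxia and hypoxia cells and at 67.5 ± 42.7 and 372 ± 73.1 in the EVs (SD, n = 3 each, log2 fold change in EVs 2.70, SE 0.44, limma adjusted p = 0.00382). LCP2 (3.00), PCARE (2.95), TCEAL2 (2.92), DGKG (2.75), STAB2 (2.70), TRPV6 (2.69), A2ML1 (2.58) and NXF3 (2.45) rose beside the higher density on low genes, which was 0.707 in normoxia EVs and 2.15 in hypoxia EVs. Most hypoxia genes that rose in cells did not pass in EVs, with log2 fold changes of -0.19 (SE 0.21) for VEGFA, 0.12 (SE 0.24) for SLC2A1, 0.30 (SE 0.26) for BNIP3, -0.10 (SE 0.23) for LDHA and 0.38 (SE 0.44) for PDK1. HIF1A, which encodes the HIF-1 alpha subunit, fell by 0.83 (limma adjusted p = 0.0497).

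The HIF list had 1 of 48 genes past the threshold in EVs, JMJD6 at -0.73, and none adjusted over the list alone. At an unadjusted limma p under 0.05, 5 were higher and 1 lower, and edgeR and DESeq2 each called 1 lower. Its median was 0.23 and its mean 0.26 while camera pointed down (adjusted p = 0.774), and the median was 0.79 with equal totals, under which 9 rose, and -0.68 with the background removed. Ribosomal protein genes fell in 40 of 78 cases and in 68 adjusted over the list alone, RPS21 by 1.12 and RPL18 by 0.93 (median -0.71, camera adjusted p = 9.79e-29, adjusted p = 0.224 with an estimated correlation). With equal totals 2 of them fell (median -0.14), and with the background removed as well the median turned to 0.02. Proliferation genes fell in 20 of 41 cases and in 32 adjusted over the list alone, AURKB by 1.07 and CENPF by 0.93 (median -0.76, -0.19 with equal totals, camera adjusted p = 3.22e-18). OXPHOS genes fell in 8 of 45 cases and in 13 adjusted over the list alone, ATP5F1B by 0.97 (median -0.56, 0.01 with equal totals, camera adjusted p = 2.41e-08). Stress response genes fell in 6 of 27 cases, and 15 were lower and 1 higher adjusted over the list alone, with CEBPB at -1.11, SESN2 at -0.89 and ATF4 at -0.85 (median -0.63, -0.07 with equal totals, camera adjusted p = 1.16e-08). Small structured RNAs fell in 7 of 17 cases and in 9 adjusted over the list alone (median -0.97, -0.42 with equal totals, camera adjusted p = 3.26e-09). EV biogenesis genes fell in 6 of 30 cases, and 8 were lower and 1 higher adjusted over the list alone, with CHMP4B at -0.84 and ARF6 at -0.78 (median -0.50, 0.07 with equal totals, camera adjusted p = 1.35e-05). Cholesterol synthesis genes fell in 2 of 25 cases, also adjusted over the list alone, SQLE by 1.02 and FDFT1 by 0.87 (median -0.42, 0.15 with equal totals, camera adjusted p = 0.00575). Of the eIF4E-sensitive mRNAs 5 of 20 fell, and 8 were lower and 1 higher adjusted over the list alone, MDM2 at -1.02 and RHOA at -0.86 (median -0.46, 0.10 with equal totals, camera adjusted p = 3.09e-05). These lists, ribosomal proteins apart, each had an adjusted p = 0.224 with an estimated correlation as well.

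Glycolysis had 3 of 20 genes lower and 1 higher (4 and 1 adjusted over the list alone), PFKP at -0.86, LDHB at -0.71, TPI1 at -0.66 and ENO2, the neuronal enolase, at 1.01 (median -0.42, 0.15 with equal totals, camera adjusted p = 0.00113, adjusted p = 0.268 with an estimated correlation). Histones fell in 5 of 17 cases, and 6 were lower and 1 higher adjusted over the list alone, H1-4 at -0.98 (median -0.62, -0.05 with equal totals, camera adjusted p = 7.15e-05, adjusted p = 0.253 with an estimated correlation). Homologous recombination and mismatch repair genes fell in 3 of 24 cases, also adjusted over the list alone, PALB2 by 0.98 and BRCA1 by 0.89 (median -0.47, 0.10 with equal totals, camera adjusted p = 6.73e-06, adjusted p = 0.235 with an estimated correlation). Beside the density on low genes, liver markers rose in 2 of 14 cases, TF by 2.13 and APOB by 2.26, and in 5 adjusted over the list alone (median 2.06, camera adjusted p = 0.0033, adjusted p = 0.308 with an estimated correlation). Blood markers passed in 0 of 16 cases with limma. At an unadjusted p under 0.05 4 were higher, edgeR and DESeq2 called 0, and 3 were higher adjusted over the list alone (median 1.31, camera adjusted p = 0.0248, adjusted p = 0.224 with an estimated correlation). No list kept a camera call in EVs with an estimated correlation. Interferon genes rose in 4 of 31 cases, also adjusted over the list alone, with MX2 at 1.60, ISG20 at 1.31 and RSAD2 at 2.36 (median 0.58, -0.40 with the background removed, camera adjusted p = 0.165). Nuclear-retained lncRNAs had 2 of 17 higher and 3 lower (2 and 4 adjusted over the list alone), MEG3 at 1.74, SNHG1 at -1.30 and MALAT1 at -1.20, with a median of -0.05 (0.51 with equal totals) and a mean of 0.10 (camera adjusted p = 0.16). The construct genes did not pass (0 of 3 with limma, also adjusted over the list alone and at an unadjusted p under 0.05, 0 with edgeR and 3 lower with DESeq2). They stood at -0.69 (SE 1.29) for EIF4E, -0.72 (SE 1.18) for YTHDF1 and -0.55 (SE 0.78) for CD9. For all 3 each hypoxia EV library lay below each normoxia EV library on the deposited scale, CD9 at 244124 to 333935 against 378570 to 455824, and limma's SE for these high genes exceeds the spread of their libraries. With equal totals EIF4E stood at -0.12, YTHDF1 at -0.15 and CD9 at 0.02. The list's median was -0.69 (0.13 with the background removed and equal totals, camera adjusted p = 0.344, and 0.00502 without normoxia EV replicate 3).

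Of 27904 genes tested in EVs 1586 rose and 1846 fell (limma), 1542 and 461 of them by at least 2-fold, around a median of 0.60, and the groups did not overlap for 10579 genes (37.9%, against 10% by chance). The split moves with the scaling, to 4255 higher and 189 lower with equal totals (median 1.13), 1239 and 2378 with TMM (0.53), 1307 and 2446 with median of ratios within the fit (0.49). It was 1026 and 2477 with edgeR and 1552 and 2990 with DESeq2. With the background removed it was 212 and 3842 (median -0.64), and with equal totals besides 114 and 193 (0.15). It also rests on single libraries. Without normoxia EV replicate 1 there were 389 higher and 247 lower, without replicate 2 0 and 7, and without replicate 3 6144 and 3934. Without hypoxia EV replicate 1 there were 129 and 279, without replicate 2 46 and 121, and without replicate 3 4 and 32. Of the 73 named genes past the threshold, 1, SNORD17, kept its call without each library.

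EVs were compared with cells over both conditions to see how extracellular RNA differs from the RNA of its source. Mucin genes, which encode heavily glycosylated proteins of epithelia, led the genes higher in EVs. MUC4 (ENSG00000145113, chromosome 3, 195746765 to 195812277, GRCh38) stood at 71.0 ± 7.98 and 108 ± 34.1 in normoxia and hypoxia cells and at 3689 ± 343 and 4605 ± 183 in the EVs (SD, n = 3 each, log2 fold change 5.57, SE 0.13, limma adjusted p = 1.92e-16). MUC5AC (5.40), MUC17 (5.06), MUC6 (4.71) and MUC5B (4.44) were higher too, together with PLA2G2F (5.68), GOLGA6L2 (5.45), the keratin gene KRT9 (4.80), TCHH, the hair follicle protein trichohyalin (4.74), and EVPL (4.55). Lower in EVs was OGT, the O-GlcNAc transferase (ENSG00000147162, chromosome X, 71533083 to 71575897), at 2673 ± 181 and 2900 ± 42.4 in cells and 236 ± 13.6 and 169 ± 26.7 in EVs (SD, n = 3 each, log2 fold change -3.80, SE 0.11, limma adjusted p = 1.25e-15). STARD4 (-4.30), VPS13A (-3.80), VMA21 (-3.77), CBX5 (-3.74), TMED7 (-3.67), PAICS (-3.56), HNRNPA3 (-3.50), the transferrin receptor gene TFRC (-3.44) and the desaturase gene SCD (-3.35) were lower as well. Cells and EVs did not overlap in any library for MUC4, OGT or the construct genes. The latter were higher in EVs, CD9 by 1.97 (SE 0.19, limma adjusted p = 2.47e-08), YTHDF1 by 1.76 (SE 0.26, limma adjusted p = 5.42e-06) and EIF4E by 1.63 (SE 0.29, limma adjusted p = 3.91e-05). With the normoxia libraries alone YTHDF1 (2.14) and EIF4E (2.02) did not pass. VEGFA did not differ past the threshold (0.07, limma adjusted p = 0.486) but this mean joins opposite differences. VEGFA lay above cells in the normoxia libraries alone (0.72) and below them in the hypoxia libraries alone (-0.57) and with TMM (-0.27).

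Most lists of genes active in the cells were lower in EVs. The count adjusted over the list alone was the same as over all genes unless given. Cholesterol synthesis had 21 of 25 lower and 2 higher, SQLE at -2.68 (median -1.57, camera adjusted p = 5.97e-07). Nuclear-retained lncRNAs had 13 of 17 lower and 2 higher, NEAT1 at -3.52 and OIP5-AS1 at -2.79 (median -1.44, camera adjusted p = 0.000169). These 2 calls held with an estimated correlation (adjusted p = 0.0375 each). OXPHOS genes were lower in 45 of 46 cases, COX7C at -2.86 and ATP5F1B at -2.56 (median -1.92, camera adjusted p = 1.15e-16, adjusted p = 0.0866 with an estimated correlation). Ribosomal protein genes were lower in 60 of 78 cases and higher in 6, RPL9 at -2.73 and RPS3 at -2.41 (median -1.09, camera adjusted p = 1.64e-13, adjusted p = 0.247 with an estimated correlation). Proliferation genes were lower in 30 of 41 cases and higher in 1, BUB1 at -2.55 (median -1.10, camera adjusted p = 6.96e-09, adjusted p = 0.219 with an estimated correlation). Small structured RNAs had 11 of 17 lower and 3 higher, the vault RNA gene VTRNA1-3 at -3.72, SCARNA10 at -3.31 and RNU5A-1 at 3.09 (median -1.31, camera adjusted p = 0.0226, adjusted p = 0.405 with an estimated correlation). Without normoxia EV replicate 3 that camera adjusted p was 0.0586. EV biogenesis had 19 of 30 lower and 7 higher, with CD63 at -2.56 and PDCD6IP, which encodes ALIX, at -2.54 (median -0.75, camera adjusted p = 0.00255, adjusted p = 0.174 with an estimated correlation). A further group of lists had an adjusted p = 0.16 with an estimated correlation. It held HIF targets, 31 of 48 lower and 6 higher, P4HA1 at -3.41, WSB1 at -2.78 and ADM at 1.20 (median -0.68, camera adjusted p = 3.24e-05). Its glycolysis genes were lower in 18 of 20 cases and higher in 2, LDHA at -3.33 (median -1.08, camera adjusted p = 6.46e-06). It also held histones, 15 of 17 lower, H1-2 at -2.45 (median -2.01, camera adjusted p = 3.88e-07), and homologous recombination and mismatch repair, 21 of 24 lower, FANCD2 at -2.36 (median -1.36, camera adjusted p = 3.77e-08). Of its eIF4E-sensitive mRNAs 15 of 20 were lower and 2 higher, RHOA at -2.37 (median -0.96, camera adjusted p = 0.000169). Its blood markers were higher in 11 of 12 cases and in 12 adjusted over the list alone, SLC4A1 at 3.95 and CD3E at 3.66 (median 2.10, camera adjusted p = 0.00338). Only 4 of the 20 blood markers passed the filter in the cell libraries alone. Most of the 12 thus entered through their EV values, which favoured this direction in advance. Stress response did not pass camera (8 of 27 higher and 14 lower, median -0.44, adjusted p = 0.16), with the stress-induced genes DDIT3 at 2.14 and PPP1R15A at 1.52 and the serine synthesis gene PSAT1 at -2.36. Nor did interferon response, with 13 of 31 higher and 5 lower, 13 and 4 adjusted over the list alone, OASL at 3.55 and MX2 at 3.01 (median 0.56, -1.49 with the background removed, camera adjusted p = 0.32).

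Liver markers were higher in 11 of 12 cases, SERPINA1 at 3.35 and TF at 2.31 (median 2.52, camera adjusted p = 0.00741, adjusted p = 0.253 with an estimated correlation). Here too 4 of the 17 passed the filter in the cell libraries alone, so the direction was favoured in advance. With the background removed 4 blood markers were higher (median 0.89) and the liver median was 1.42. The construct genes were higher in 3 of 3 cases (median 1.76, camera adjusted p = 0.0449, adjusted p = 0.253 with an estimated correlation). As a list of 3 genes they lost camera's call without any of 9 libraries. The adjusted p was 0.0601 without normoxia cell replicate 1, 0.0599 without replicate 2, 0.0572, 0.0578 and 0.0555 without hypoxia cell replicates 1, 2 and 3. It was 0.0606 without normoxia EV replicate 2, and 0.0620, 0.0746 and 0.0843 without hypoxia EV replicates 1, 2 and 3.

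**Figure D4:**
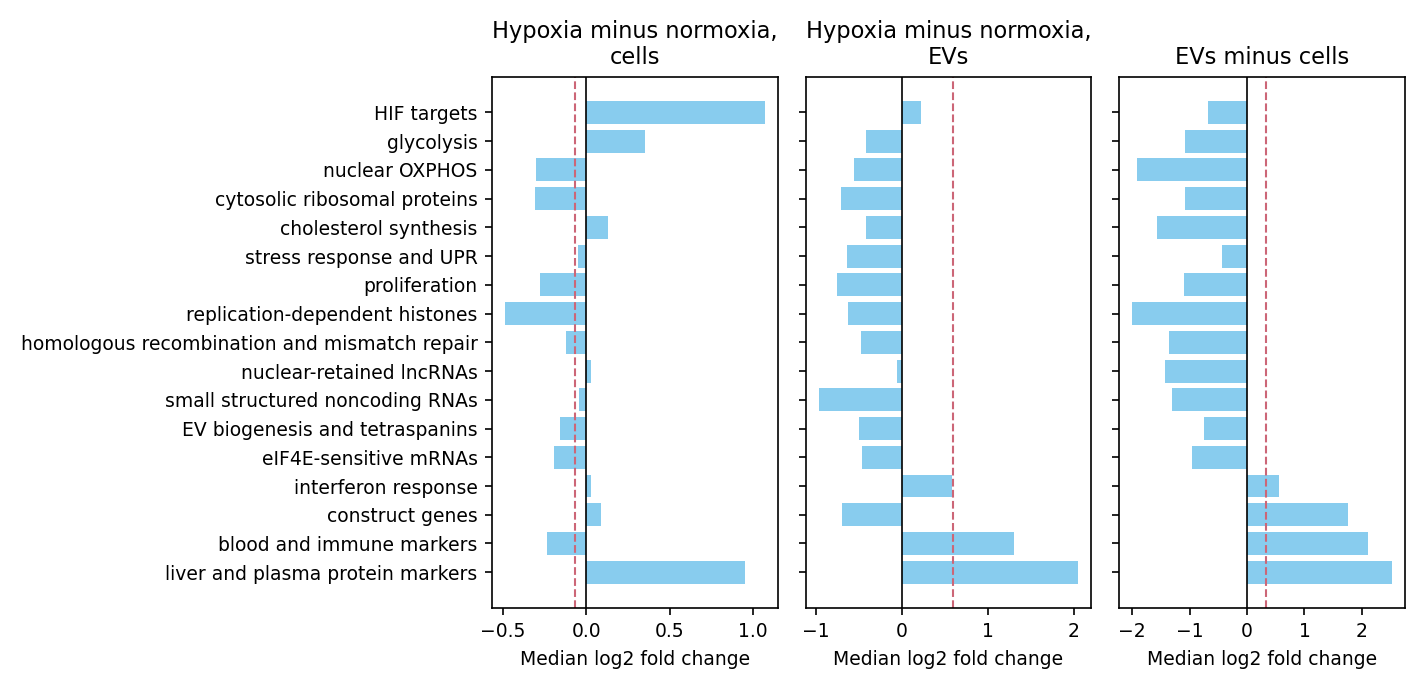
Median log2 fold change of each gene list for hypoxia minus normoxia in cells, hypoxia minus normoxia in EVs, and EVs minus cells, with the median of all genes tested as a dashed line (-0.07, 0.60 and 0.32). HIF targets stand at 1.07 in cells and 0.23 in EVs, and with equal totals the EV medians of glycolysis, OXPHOS, cholesterol synthesis, lncRNAs, EV biogenesis, eIF4E-sensitive mRNAs and DNA repair turn positive, while with the background removed those of HIF targets and interferon response turn negative. In cells the small medians of stress response, small RNAs and DNA repair turn positive with equal totals, and in EVs minus cells that of interferon response turns negative with the background removed. Equal totals also move the median of all genes, to 0.06 in cells and 1.13 in EVs. Removing the background moves it to -0.64 in EVs and -0.88 in EVs minus cells.

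Of 24171 genes tested 10414 were higher and 7680 lower in EVs than in cells (limma), 8968 and 5145 by at least 2-fold, around a median of 0.32 (-0.01 with TMM, under which 8875 were higher and 9347 lower). With the background removed the split turned to 3848 higher and 10151 lower (median -0.88), and with equal totals besides to 4731 and 9267. It was 5397 and 6027 with the normoxia libraries alone. Across genes, the Spearman correlation of levels had a median of 0.973 between libraries of a cell group, 0.891 within normoxia EVs and 0.895 within hypoxia EVs. Normoxia EV replicate 3 correlated with hypoxia EV replicates 1 and 2 at 0.896 and 0.895, above its 0.859 with normoxia EV replicate 1. Between cell and EV libraries the median was 0.823 in normoxia and 0.710 in hypoxia (24171 genes, which are not independent replicates). Over 16823 protein-coding genes the EV minus cell fold change correlated across genes with GC content (Spearman 0.48), transcript length (-0.24) and the level in cells (-0.73). The level in cells is subtracted in that fold change, so part of the last coefficient is built in.

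The hypoxia responses of cells and EVs were set side by side to see how far EV RNA followed cellular RNA, and their difference was tested. DDIT4, a stress-induced inhibitor of mTOR signalling (ENSG00000168209, chromosome 10, 72273920 to 72276036, GRCh38), stood at 189 ± 34.4 and 765 ± 36.6 in normoxia and hypoxia cells and at 322 ± 93.8 and 235 ± 61.5 in EVs (SD, n = 3 each, difference of log2 fold changes -2.47, SE 0.32, limma adjusted p = 0.00154). VEGFA stood at 1185 ± 97.1 in normoxia EVs and 1035 ± 45.6 in hypoxia EVs (difference -1.29, SE 0.19, limma adjusted p = 0.00284). The difference was negative too for EPS8L2 (-2.41), FOS (-2.04), CITED2 (-1.98), PPFIA4 (-1.85), PGK1 (-1.69) and STC2 (-1.34), which rose in cells and did not pass in EVs. SAT1 (-1.95) and MALAT1 (-2.12) rose in cells and fell in EVs. SNORD17 had the difference -3.13 (SE 0.28, limma adjusted p = 1.08e-05). TRIM66 (ENSG00000166436, chromosome 11, 8612037 to 8682694) went the other way, from 148 ± 16.7 to 77.2 ± 2.03 in cells and from 111 ± 24.4 to 299 ± 12.3 in EVs (SD, n = 3 each, difference 2.37, SE 0.33, limma adjusted p = 0.00181). BTN3A2 (2.51) also fell in cells and rose in EVs. ENTPD5 (2.45) and PRTG (2.38) rose in EVs and did not pass in cells, while RORB (2.57) and MYC (0.96) fell in cells and did not pass in EVs.

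Of 48 HIF targets 42 had a difference below 0, which passed the threshold for 18 and for 26 adjusted over the list alone (median -0.97, camera adjusted p = 8.47e-18), and theirs was the 1 call that held with an estimated correlation (adjusted p = 0.0152). Glycolysis followed with 6 of 20 lower and 12 adjusted over the list alone (median -0.84, camera adjusted p = 4.07e-11). Cholesterol synthesis had 2 of 25 genes lower, SQLE at -1.44, and 7 lower and 1 higher adjusted over the list alone (median -0.42, 0.02 with equal totals, camera adjusted p = 0.000518). Both had an adjusted p = 0.137 with an estimated correlation. Stress response had 4 of 27 lower, ATF3 at -1.35 and SESN2 at -1.06, and 17 lower and 1 higher adjusted over the list alone (median -0.59, camera adjusted p = 2.49e-09). Small structured RNAs had 5 of 17 lower and 7 adjusted over the list alone (median -0.71, camera adjusted p = 1.63e-06). EV biogenesis had 0 of 30 with limma and 1 lower adjusted over the list alone. At an unadjusted limma p under 0.05 it had 8 lower, with edgeR 4 and with DESeq2 5 (median -0.33, 0.11 with equal totals, camera adjusted p = 0.000857). These 3 lists had an adjusted p = 0.179 with an estimated correlation. Ribosomal protein genes had 1 of 78 lower, RPS19 at -0.95, and none adjusted over the list alone (median -0.43, 0.01 with equal totals, camera adjusted p = 3.05e-12, adjusted p = 0.275 with an estimated correlation). Proliferation had 3 of 41 lower and 8 adjusted over the list alone (median -0.40, 0.04 with equal totals, camera adjusted p = 1.17e-09, adjusted p = 0.274 with an estimated correlation). Homologous recombination and mismatch repair had 0 of 24 past the threshold with limma, also adjusted over the list alone. At an unadjusted p under 0.05 it had 7 lower, with edgeR 4 and with DESeq2 2 (median -0.35, 0.09 with equal totals, camera adjusted p = 0.000245, adjusted p = 0.275 with an estimated correlation).

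Of eIF4E-sensitive mRNAs 1 of 20 was higher and 1 lower, MYC and VEGFA, with 1 and 2 adjusted over the list alone (median -0.16, 0.28 with equal totals, camera adjusted p = 0.00735, adjusted p = 0.275 with an estimated correlation). Without normoxia EV replicate 1 camera's adjusted p was 0.0603. OXPHOS had 0 of 46 past the threshold with limma, also adjusted over the list alone, and 3 higher and 7 lower at an unadjusted p under 0.05. With edgeR 5 were lower, and with DESeq2 2 higher and 5 lower (median -0.23, 0.21 with equal totals, camera adjusted p = 0.0209, adjusted p = 0.459 with an estimated correlation). Its camera adjusted p was 0.265 without normoxia EV replicate 1, 0.0512 without replicate 2 and 0.0901 without hypoxia EV replicate 3. Blood markers had 0 of 12 past the threshold with limma, also adjusted over the list alone. At an unadjusted p under 0.05 1 was higher, with edgeR 0 and with DESeq2 1 (median 1.31, camera adjusted p = 0.0407, adjusted p = 0.275 with an estimated correlation). Camera's adjusted p for them was 0.0824 without hypoxia cell replicate 2, 0.112 and 0.0545 without normoxia EV replicates 1 and 2, and 0.0730 and 0.0803 without hypoxia EV replicates 1 and 2. Liver markers had 1 of 12 higher, TF at 2.42, also adjusted over the list alone (median 1.23, camera adjusted p = 0.0425, adjusted p = 0.377 with an estimated correlation). Their camera adjusted p was 0.0668 without normoxia cell replicate 3, 0.0815 without hypoxia cell replicate 2, 0.265 and 0.0781 without normoxia EV replicates 1 and 2, and 0.0669 and 0.0694 without hypoxia EV replicates 1 and 2. Nuclear-retained lncRNAs had 3 of 17 lower, MALAT1, NEAT1 and SNHG1, and 4 lower and 2 higher adjusted over the list alone, with a median of -0.24 (0.20 with equal totals) and a mean of 0.00 (camera adjusted p = 0.0553). Camera called them without normoxia cell replicates 1 (0.0467) and 2 (0.0284), hypoxia cell replicate 2 (0.0476) and normoxia EV replicate 1 (0.0464). Histones had 0 of 17 past the threshold with limma and 1 higher adjusted over the list alone, 3 being higher and 1 lower at an unadjusted p under 0.05, 0 with edgeR and 1 higher with DESeq2. Their median was -0.11 (0.33 with equal totals) and their mean 0.28 (camera adjusted p = 0.86, and 0.0401 without normoxia EV replicate 3). Interferon response had 0 of 31 with limma, also adjusted over the list alone, 4 higher and 1 lower at an unadjusted p under 0.05, 0 with edgeR and 1 lower with DESeq2 (median 0.38, camera adjusted p = 0.239). The construct genes had 0 of 3 with limma, also adjusted over the list alone and at an unadjusted p under 0.05, while edgeR and DESeq2 each called 3 lower (median -0.76, camera adjusted p = 0.076, and 0.000419 without normoxia EV replicate 3).

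In all, 107 genes had a higher and 452 a lower response in EVs than in cells, of 24171 tested (limma), around a median of 0.23. TMM gave 170 and 1785 (median 0.03) and equal totals 475 and 151 (0.66). The counts rest on single libraries. Without normoxia cell replicates 1, 2 and 3 they were 7 and 46, 2 and 42, and 8 and 75, and without hypoxia cell replicates 1, 2 and 3 they were 8 and 65, 4 and 34, and 7 and 41. Without normoxia EV replicates 1, 2 and 3 they were 195 and 354, 97 and 206, and 2280 and 3158, and without hypoxia EV replicates 1, 2 and 3 they were 58 and 310, 33 and 185, and 28 and 182. Kept without each library were 12 of 40 named calls, DDIT4, VEGFA, PGK1, STC2, MALAT1, SNORD17 and TRIM66 among them.

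Across 16514 genes tested in both, the hypoxia fold changes in cells and EVs, which share no library, correlated with a Spearman coefficient of 0.34 and a Pearson coefficient of 0.35 (genes are not independent replicates). Both fold changes also fell with the level in cells. Their Spearman coefficients with it were -0.35 in cells (13884 protein-coding genes) and -0.78 in EVs (17363). Such a shared trend can give a positive coefficient and more overlap than independent lists. The values here therefore do not show that EVs followed cells gene by gene. Of 5199 genes that changed in cells 78.1% had the same sign in EVs. Genes that rose in cells had the same sign in 59.7% of 1345 cases and a median of 0.23 in EVs. Those that fell in cells had it in 84.6% of 3854 cases and a median of -0.55. Equal totals turned this round, with the same sign in 76.5% of the genes that rose and 51.6% of those that fell in cells, and EV medians of 0.52 and -0.01. The EV median of all genes was -0.15 (0.41 with equal totals). In both, 114 genes rose against 63.3 expected of independent lists, and 889 fell against 430.3. With equal totals 487 rose in both (322 expected) and 49 fell in both (23.3 expected). Opposite calls were made for 96 genes that rose in cells and fell in EVs and for 17 that fell in cells and rose in EVs. With equal totals these were 31 and 53, and with TMM 177 and 8.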

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

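The results below were picked because the hypoxia response of the RNA differed between EVs and cells in a tested interaction (limma). Values are log2 differences, EV response minus cell response, and medians for lists. The difference passed the threshold for 107 genes with a higher and 452 with a lower response in EVs, and these counts rest on single libraries.

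The difference was positive for TRIM66 (2.37) and BTN3A2 (2.51), which fell in cells and rose in EVs. It was positive for ENTPD5 (2.45), PRTG (2.38) and TF (2.42), which rose in EVs and did not pass in cells, and for RORB (2.57) and MYC (0.96), which fell in cells and did not pass in EVs. It was negative for genes that rose in cells and did not pass in EVs, namely DDIT4 (-2.47), EPS8L2 (-2.41), CITED2 (-1.98), FOS (-2.04), VEGFA (-1.29), ADM (-1.55), SLC2A1 (-1.15), BNIP3 (-1.36), LDHA (-1.04), NDRG1 (-1.08), PPFIA4 (-1.85), STC2 (-1.34), PGK1 (-1.69), ALDOA (-1.25), PFKL (-1.13), ATF3 (-1.35) and NEAT1 (-0.91). SAT1 (-1.95), MALAT1 (-2.12), SQLE (-1.44), PPP1R15A (-1.02) and TK1 (-1.13) rose in cells and fell in EVs. SESN2 (-1.06), CEBPB (-1.05), RPS19 (-0.95), NUSAP1 (-0.95), BUB1 (-0.80), SNORD17 (-3.13), SNORA73B (-2.17) and RNU4-2 (-1.63) fell in EVs and did not pass in cells. SNHG1 (-1.11) fell in both, and SNORA74A (-1.58) passed in neither.

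Lists that camera called had medians of -0.97 for HIF targets, -0.84 for glycolysis, -0.71 for small RNAs and -0.59 for stress response, and 1.31 for blood and 1.23 for liver markers. With an estimated correlation HIF targets alone kept the call (camera adjusted p = 0.0152). The further lists called at the preset correlation lay at -0.43 for ribosomal proteins, -0.42 for cholesterol synthesis, -0.40 for proliferation, -0.35 for DNA repair, -0.33 for EV biogenesis, -0.23 for OXPHOS and -0.16 for eIF4E-sensitive mRNAs. With equal totals each of these 7 turned positive. That scaling also moved the median of all genes from 0.23 to 0.66, and the 7 medians stayed below it.

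Splits of the samples were chosen as a test after the counts were seen. For the interaction 4 of 100 splits gave as many genes as the real 559, the real one included, and the highest other gave 5468. That split kept the cell groups and mirrored the EV groups, so its difference is the sum of the hypoxia responses, which is the structure of the samples behind its count. The other 2 kept the EV groups and mixed the cell groups. Such splits carry the hypoxia response itself, so they decide nothing about the 559 genes. For EVs against cells 1 of 100 splits reached the real 18094, and the highest other gave 12571, so a grouping by chance is excluded. For hypoxia in cells 1 of 10 splits reached the real 5254, and for hypoxia in EVs 1 of 10 reached the real 3432, with 0 genes as the highest other in both. These splits are too few for a share under 0.05.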

How the results depend on the processing

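Of named genes past the threshold, 84 of 93 kept their call under the settings fixed before the data were examined and without each library for EVs against cells, 23 of 79 for hypoxia in cells, 1 of 73 for hypoxia in EVs and 12 of 40 for the interaction. Of lists that camera called these were 2 of 15, 2 of 9, 0 of 13 and 1 of 13. The estimated correlation weakened 13, 7, 13 and 12 of these list calls, in the same order. For hypoxia in cells the single fit of all 12 libraries weakened 56 named calls, while 72 of 79 held without each library. For hypoxia in EVs 26 of 73 held under the settings and 1 without each library. For the interaction these were 18 and 12 of 40. In cells, equal totals gave 2304 higher and 2043 lower, DESeq2 2515 lower and all 12 libraries in a single fit 59 and 25. In EVs a pseudocount of 0.5 gave 923 higher and 5 gave 2946, edgeR gave 1026 higher and DESeq2 2990 lower. There equal totals gave 4255 and 189, library weights 7543 and 4293, all 12 libraries 3819 and 4419, the removed background 212 and 3842, and with equal totals besides 114 and 193. For EVs against cells a filter of 50 left 3667 higher, the normoxia libraries alone 5397, the removed background 3848, and with equal totals 4731. For the interaction a pseudocount of 5 gave 239 higher, no filter 19 and 86, a filter of 50 735 lower, TMM 170 and 1785, equal totals 475 and 151 and library weights 1680 and 2730. There edgeR gave 185 and 1479, DESeq2 520 and 1659, the removed background 2416 lower and with equal totals 274 and 855. The replicate number as a block gave 2776 higher in EVs and 254 lower in the interaction. Deviations from the group means did not correlate by number, from -0.16 to 0.02 between cells and EVs of the same number and from -0.04 to 0.14 of different numbers. With 3 libraries per group this cannot decide whether the numbers pair cells and EVs of the same culture.

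With a library left out, cells had 1016 to 1191 higher and 3112 to 3537 lower, EVs 0 to 6144 and 7 to 3934, EVs against cells 9377 to 11240 and 7363 to 7970, and the interaction 2 to 2280 and 34 to 3158. The Spearman coefficient of the responses ran from 0.276 to 0.357 (0.244 with a filter of 50, 0.246 with the background removed and equal totals). The share of the same sign ran from 75.3% to 80.3% (64.7% with equal totals, 75.3% with TMM, 66.7% with all 12 libraries, 60.9% with the background removed and equal totals). Level correlation between cells and EVs ran from 0.794 to 0.839 in normoxia and from 0.698 to 0.715 in hypoxia (0.768 and 0.590 with a filter of 50). The construct ratio ran from 3.34 to 3.49, the ribosomal protein ratio from 0.595 to 0.639 and the low-gene density ratio from 7.66 to 9.92.

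Signs turned in a few cases. With the background removed and equal totals LDHB stood at 0.0538, TPI1 at 0.12 and ARF1 at 0.0187 in EVs. Against cells VEGFA stood at -0.27 with TMM and -0.57 in the hypoxia libraries. MX2 stood at -1.82 with the background removed and -1.68 with equal totals besides, and CYP2E1 at -1.16 and -1.09. Camera pointed up for HIF targets in EVs with equal totals (adjusted p = 0.0443) and for glycolysis in EVs with the background removed and equal totals (0.0434). In the interaction that setting turned camera up for OXPHOS (0.596), ribosomal proteins (0.000243), proliferation (0.307) and histones (0.0055).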

Other observations

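Genes that encode gel-forming and membrane mucins stood above cells in the EVs as a family. All 14 genes named MUC that were tested passed (limma), from MUC4 at 5.57 and MUC5AC at 5.40 to MUC3A at 4.20, MUC16 at 4.15 and MUC19 at 1.78. The filter used all libraries, so a gene near silent in cells was tested only where its EV values were high. This favoured the direction for such genes. With the background removed 10 stayed higher, while MUC13 (-2.10) and MUC19 (-3.43) turned negative.

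The tests of the reads on genes silent in cells were chosen after the result was seen. Those reads may come from a near-uniform background such as DNA. This was tested in the hypoxia EVs over 7 classes of such genes. The added density differed by 2.14 times from the lowest class to the highest, which such a background allows. Other values were mixed for a uniform background. Density was 0.863, 1.97 and 2.43 on protein-coding genes with cell means up to 1, of 1 to 5 and of 5 to 20. Their reads correlated with gene length at 0.01, 0.23 and 0.39 (Spearman). For olfactory receptors this was 0.14 and for lincRNAs 0.48. A difference in depth is excluded, since at equal depth hypoxia EVs still held 1.33 times the genes of normoxia EVs. RNA of blood or liver cells rich in HBB, HBA1, HBA2, ALB and APOA1 is excluded too as the main source. Together these genes held 1.11 times the density of olfactory receptors, and HBB had at most 13 reads in a library. That test held no immune marker. Of the 7 classes, blood and immune markers had the highest added density, 2.25 over 17 genes, close to 2.02 over 5698 other protein-coding genes. That does not single out RNA of immune cells, which was not tested and so is not excluded. DNA was not measured, and a treatment with DNase before the libraries would test it.

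The weaker response of HIF targets in EVs could be technical or biological. Tests chosen after the result was seen excluded scaling and few reads per gene as its sole cause, but could not decide on dilution by a background. Under equal totals, the scaling that moved it most, the median difference stayed at -0.54, with 33 of 48 genes below 0. Over 20 genes with a mean of at least 200 in the EV libraries it was -1.21 (19 below 0). With the background removed and equal totals it was -1.13 (44 of 46 genes below 0). That removal took 26.7% to 28.6% of the reads of hypoxia EV libraries and 2.58% to 14.2% of normoxia EV libraries. At the authors' scaling it can only lower the EV response, and it set low genes to 0. It therefore does not show whether dilution weakened the response. A hypothesis is that much of the EV RNA was loaded before or early in the 24 h of hypoxia and so may show an earlier state of the cells, and EVs collected at a series of times would test it.

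The mucin excess was weighed against technical accounts by tests of which those of GC content and background were chosen after the result was seen. The 14 genes had a median of 4.26 against at most 2.42 in 1000 sets matched on GC content, so GC content alone does not give it. The sets were not matched on the level in cells, which correlated with the fold change at -0.73. The family was also picked from the leading genes of these data. GC content among genes low in cells is therefore not excluded. A background that is even per kb is excluded as the sole cause, as the median of the 14 genes stayed at 3.55 with it removed. That removal took the same density per kb off every gene. A background that is uneven between genes is therefore not excluded for a family picked from the leading genes. Repeated sequence could not be told apart. The 168 most repeated genes had a median of 1.12, above most of 1000 matched sets, which had a median of 0.86 and reached 1.19. Going with it, the leading genes MUC4, MUC5B, MUC5AC, MUC17, GOLGA6L2, TCHH and MUC6 lay at percentiles 99.16 to 99.93 of repeat share. The 14 mucin genes had a median share of 27.6%, against 0% outside the 168 genes. Against it stand PLA2G2F and EVPL with 0% repeats, and MUC1 with 51.8% at 1.85 beside MUC16 with 8.91% at 4.15. Repeat share and fold change had a Spearman coefficient of -0.02 over 16823 protein-coding genes. As 72.2% of these had 0% repeats, that coefficient says little about the most repeated genes.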
